A study of Homo sapiens with 12 samples.

How the data were processed

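The measurement was mRNA sequencing of U87 cells, an established human glioblastoma cell line, in 12 libraries. The labels give 4 groups of 3 libraries: untreated cells (control), cells given the anti-seed peptide nucleic acid sgPNA-10b (PNA-10b), cells given sgPNA-21 (PNA-21), and cells given both (PNA-10b+21). A peptide nucleic acid is a synthetic strand with a peptide-like backbone, and an anti-seed one pairs with the seed of a microRNA, here miR-10b or miR-21. Per the protocols each sgPNA was given at 150 nM for 72 h in bioadhesive nanoparticles, so the combined arm carries both doses. The labels describe no arm with empty nanoparticles or with a control PNA. They also do not say whether the 3 replicates of a group were separate cultures, so each p-value measures a difference against the spread between these libraries.

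The authors deposited 1 table of raw counts per Ensembl gene, with 35741 genes and 12 columns of counts. Every value is a whole number, and the column totals differ between samples, so the deposited counts carry no normalization. HISAT2 2.1.0, SAMtools 1.7, HTSeq 0.11.0 and the genome build hg38 are listed in the submitters' processing notes. The strand setting and the annotation release are not given in the sources used here, so counts at antisense and overlapping genes are less certain. Total counts per library ran from 12846676 to 18305820. All 12 columns matched a sample, and 34564 of the genes matched the GENCODE release 29 annotation, which gave coordinates, gene types and 3′ UTR sequence. Gene names repeat for 358 entries, so genes were joined by Ensembl identifier.

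Genes were kept with the filterByExpr function of edgeR 4.0.16 at a minimum count of 10. This left 15715 genes, which hold 99.84% of all counts, and removed 20026. Libraries were scaled with TMM factors. All 12 libraries entered 1 quasi-likelihood fit with a mean per group (glmQLFit and glmQLFTest, R 4.3.3), so that the 4 groups share 1 estimate of the spread. The common biological coefficient of variation was 0.052. A gene passed the test at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. There were 7 comparisons: each treatment against control, the 3 pairs of treatments, and the interaction. The interaction is the change from PNA-10b to PNA-10b+21 minus the change from control to PNA-21, on the log2 scale, and measures departure from additive effects. Errors of log2 fold changes are standard errors of the fit with 3 libraries per group. Levels are CPM, counts scaled by library size, with the standard deviation (SD) of 3 libraries.

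The comparisons, the tests, 39 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Of the 996 list entries, 40 matched no gene of the table. The mitochondrially encoded genes are absent from the deposited counts, which left 38 lists to test. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation and edgeR's fry. The rule named, in each comparison against control, the 10 largest rises and 10 largest falls past the threshold with a mean log2 CPM of at least 1 and no overlap between treated and control libraries. Between treatments and in the interaction it named 5 in each direction. It also named up to 4 members of a described list by smallest p-value, and 16 reported targets of miR-21 or miR-10b. Genes on the Y chromosome and genes without a symbol were not named.

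Where a microRNA is blocked, transcripts with a match to its seed can rise. Genes were therefore sorted by whether the longest annotated 3′ UTR holds a 7mer-m8 or 8mer site of miR-21-5p (ATAAGCT) or miR-10b-5p (ACAGGGT). This was possible for 12224 tested genes. The median log2 change of genes with a site was compared with that of genes without, by camera. Each 7mer was also ranked among 15934 by the same difference after a regression on UTR length and GC content. Tested on simulated data for PNA-21 against control, an added shift of 0.1 log2 put the miR-21 site at rank 1, a shift of 0.03 at rank 586, and no shift at rank 14411. With no shift the recovered difference was -0.0144. The simulation shuffled the log2 changes over genes, with a single draw per shift. It thus keeps neither their link to UTR sequence nor the error between libraries, and can overstate what the ranking detects. Mature microRNAs were not measured by this assay.

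The gene test was also tested on simulated data in which 200 genes were changed by known factors. These were drawn from genes with an average log2 CPM of at least 1, so the recovery does not cover genes below that level. Against control, the simulated changes of 1.25-fold were recovered for 58.2% of genes in PNA-10b, 52.2% in PNA-21 and 53.7% in PNA-10b+21. Recovery was 80.6%, 82.1% and 82.1% at 1.5-fold, and 95.5%, 95.5% and 92.4% at 2-fold, with 9, 9 and 12 false calls. For PNA-10b+21 against PNA-21, recovery was 62.7%, 77.6% and 95.5% at these folds, with 12 false calls.

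Alternatives were median-of-ratios scaling, DESeq2 1.42.0, limma voom, no filter, a filter of 1 CPM in 3 libraries, a fit on the compared groups alone, the replicate number as a block, and leaving out each library. The fits on fewer libraries kept the 15715 genes. That choice was made after a first run, and the values with genes filtered anew are given beside it. Replicate numbers gave no clear pairing and were left out of the main fit. Over 18 pairs of libraries with the same number, correlations of the residuals ran from -0.058 to 0.109, and over other numbers from -0.087 to 0.118. Of the 12 libraries, 6 correlated best with a library of their own number. No library was left out of the main comparisons. TMM and median-of-ratios factors differed by at most 0.004 log2.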

Results

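The counts describe the polyadenylated RNA of U87 glioblastoma cells left untreated or given sgPNA-10b, sgPNA-21 or both for 72 h, with 3 libraries in each of the 4 groups. Total counts per library ran from 12846676 to 17053150 in control, 14026933 to 16969787 in PNA-10b, 14634738 to 18305820 in PNA-21 and 14102709 to 17098686 in PNA-10b+21. The 10 most abundant genes held 4.83% ± 0.358 (SD, n = 3) of counts in control, 4.19% ± 0.241 in PNA-10b, 3.63% ± 0.127 in PNA-21 and 3.80% ± 0.127 in PNA-10b+21. The first principal component carried 30.2% of the variance. On it the control libraries lay from -32.4 to -20.3, PNA-10b from -9.2 to -0.5, PNA-21 from 11.8 to 18.6 and PNA-10b+21 from 8.4 to 20.8. Expression of 15715 genes was compared.

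The comparison of PNA-10b with control asks what sgPNA-10b in nanoparticles changed in U87 cells. Control cells were untreated, so any effect of the nanoparticles or of handling is part of each change against control. The enzymes of cholesterol synthesis rose, among them HMGCS1 (log2 fold change 0.65 ± 0.06 SE), MVD (0.44 ± 0.05) and FDFT1 (0.35 ± 0.05), which act from the start of the mevalonate pathway to the making of squalene. The fibrillar collagen genes COL3A1 (-1.69 ± 0.17), COL1A1 (-0.53 ± 0.07) and COL1A2 (-0.51 ± 0.07) fell. So did the immediate early genes FOSB (-1.46 ± 0.18), NR4A1 (-1.26 ± 0.20) and FOS (-0.85 ± 0.14), transcription factors that respond to growth stimuli. The amino acid genes PSAT1 (0.65 ± 0.10, serine synthesis) and SLC7A5 (0.76 ± 0.12, an amino acid transporter) rose, as did TRIB3 (0.64 ± 0.10), a target of the stress factor ATF4. COL3A1 (ENSG00000168542, chromosome 2 from 188974320 to 189012746 in hg38) went from 79.6 ± 19.0 CPM (SD, n = 3) in control to 24.7 ± 3.97.

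By list, 18 of 25 cholesterol genes rose in PNA-10b and 0 fell, with 21 higher when adjusted over the list alone. This call held with an estimated correlation (adjusted p = 0.00235). Of 29 ATF4 response genes 15 rose and 0 fell, and 21 were higher and 1 lower adjusted over the list alone. Of 30 genes of the G2 and M phases 24 rose (29 adjusted over the list alone), with BUB1 (0.32 ± 0.06) and AURKA (0.33 ± 0.06) among them. Of 29 extracellular matrix genes 14 fell (19 adjusted over the list alone). Of 22 immediate early genes 1 rose and 8 fell (2 and 9 adjusted over the list alone). Of 13 genes of fatty acid synthesis 5 rose, with FADS2 at 0.49 ± 0.09 (9 higher and 2 lower adjusted over the list alone). Of 24 matrix proteases and inhibitors 1 rose and 7 fell, with TIMP2 at -0.28 ± 0.05 (3 and 11 adjusted over the list alone). These 6 lists passed camera at the preset correlation, and each had adjusted p = 0.0737 with an estimated correlation. Of 22 genes of the TGF-beta and SMAD list 8 fell, with the matricellular gene CCN2 at -0.84 ± 0.15 (3 higher and 12 lower adjusted over the list alone). Of 32 S phase genes 8 rose (22 adjusted over the list alone). Both lists had adjusted p = 0.211 with an estimated correlation. Replication-dependent histone genes kept their call with an estimated correlation (adjusted p = 0.0393): 3 of 10 fell, 6 adjusted over the list alone, with HIST1H4H at -1.05 ± 0.23. Their list mean was low, at 2.33, 2.32 and 2.27 log2 CPM in the control libraries, and 10 of 17 matched members were tested. How fully an assay of polyadenylated RNA captures these transcripts was not tested.

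The list counts in PNA-10b rested on few libraries. Without PNA-10b replicate 2 there were 4 G2 and M phase, 1 S phase, 7 ATF4, 2 TGF-beta, 2 protease and 0 histone genes. Without control replicate 1 the counts were 12 G2 and M phase, 2 S phase, 4 TGF-beta, 1 protease and 3 fatty acid genes, and without control replicate 3 they were 9, 1, 4 and 3 for the first 4 of these lists. Without PNA-10b replicate 1 there were 15 G2 and M phase genes.

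In all, 432 genes were higher and 587 lower in PNA-10b than in control, or 6.5% of the genes tested, with a median absolute log2 change of 0.32. A change of at least 2-fold was found for 13 higher and 45 lower genes. Among the largest rises were ATP6V0D2, a subunit of the vacuolar proton pump (1.33 ± 0.22), the serpin SERPINB2 (0.99 ± 0.23), PLCXD2 (0.93 ± 0.22) and C6orf223 (0.89 ± 0.10), and the noncoding RNAs LINC02392 (1.12 ± 0.24), LINC01723 (1.01 ± 0.30) and LINC01363 (0.90 ± 0.22). The largest falls were in RANBP3L (-2.29 ± 0.37), COL3A1, the hyaluronan-binding protein CEMIP (-1.67 ± 0.20), TMEM119 (-1.66 ± 0.21), the vessel factor ANGPT2 (-1.56 ± 0.22), the collagen receptor ITGA11 (-1.51 ± 0.15), FOSB, CYTIP (-1.29 ± 0.19), NR4A1 and SLITRK6 (-1.21 ± 0.17). EIF3CL, METRNL and the pseudogene SMG1P5 also met the rule, but EIF3CL stood at 41.4 ± 53.1 CPM (SD, n = 3) in PNA-10b and METRNL did not pass in DESeq2. EIF3CL and SMG1P5 have near-identical paralogs, and whether reads were shared with them was not examined. The counts fell to 177 higher and 298 lower without control replicate 1, 151 and 269 without control replicate 3, and 99 and 207 without PNA-10b replicate 2. Without control replicate 1, LINC02392 (0.98), LINC01723 (0.81), SERPINB2 (0.98), PLCXD2 (0.72), LINC01363 (0.88) and SMG1P5 (0.67) no longer passed. Without PNA-10b replicate 2, LINC01723 (1.00), SERPINB2 (0.99), PLCXD2 (0.83), LINC01363 (0.83) and SMG1P5 (0.82) did not pass either. LINC01723 was also lost without control replicate 2 (0.94), PNA-10b replicate 1 (0.94) or 3 (1.10), PNA-21 replicate 2 (1.01) and PNA-10b+21 replicate 1 or 2 (1.01 each). LINC02392 was also lost without control replicate 3 (0.95) and LINC01363 without control replicate 2 (0.75). METRNL was lost without control replicate 1 (1.37) or 3 (1.47) and without PNA-10b replicate 2 (1.30).

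The comparison of PNA-21 with control asks the same of sgPNA-21 in nanoparticles, again beside untreated cells. Genes of hypoxia and glycolysis fell nearly as a block: 28 of 30 were lower and 0 higher (28 adjusted over the list alone), with a list median of -0.52 (adjusted p = 0.138 with an estimated correlation). CA9, a carbonic anhydrase induced by low oxygen, changed by -0.98 ± 0.08, the glycolytic enzyme ALDOC by -0.80 ± 0.06, the collagen prolyl hydroxylases P4HA1 and P4HA2 by -0.75 ± 0.07 and -0.73 ± 0.06, and the vessel growth factor VEGFA by -0.64 ± 0.08. Of 29 matrix genes 24 fell and 1 rose (25 and 1 adjusted over the list alone), with COL5A1 at -1.13 ± 0.07, COL1A1 at -0.87 ± 0.07, the crosslinking enzyme LOXL2 at -0.76 ± 0.06 and COL6A3 at -0.72 ± 0.07 (adjusted p = 0.103 with an estimated correlation). Cholesterol genes rose again, 21 of 25 (21 adjusted over the list alone), with INSIG1 at 0.63 ± 0.06, FDFT1 at 0.49 ± 0.05 and DHCR7 at 0.48 ± 0.05, and this call held (adjusted p = 0.0393 with an estimated correlation). Of the proliferation lists, 28 of 30 G2 and M phase genes (28 adjusted over the list alone) and 29 of 32 S phase genes (31 adjusted over the list alone) rose, among them AURKB (0.62 ± 0.08), CDK1 (0.50 ± 0.06), RFC3 (0.67 ± 0.07), RRM2 (0.53 ± 0.06) and E2F1 (0.54 ± 0.07). These had adjusted p = 0.200 with an estimated correlation for G2 and M phase and 0.213 for S phase genes.

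Further lists passed camera in PNA-21 at the preset correlation only. Of 18 angiogenic factors 3 rose and 8 fell (3 and 10 adjusted over the list alone), with ANGPT1 at -1.27 ± 0.10 and NRP1 at -0.39 ± 0.05 (adjusted p = 0.223 with an estimated correlation). Of 20 endoplasmic reticulum chaperones 1 rose and 9 fell, with P4HB at -0.34 ± 0.05 and HERPUD1 at -0.31 ± 0.05 (1 and 9 adjusted over the list alone, adjusted p = 0.197 with an estimated correlation). Of 22 TGF-beta and SMAD genes 2 rose and 11 fell, with TGFB2 at -0.73 ± 0.11 and LTBP3 at -0.55 ± 0.06 (2 and 12 adjusted over the list alone, adjusted p = 0.245 with an estimated correlation). Of 17 ERK feedback genes 9 rose and 1 fell, with ETV4 at 0.62 ± 0.08 (10 and 1 adjusted over the list alone, adjusted p = 0.213 with an estimated correlation). Of 13 fatty acid genes 7 rose and 1 fell, with FASN, the fatty acid synthase, at 0.57 ± 0.05 (8 and 1 adjusted over the list alone, adjusted p = 0.213 with an estimated correlation). Of 23 NRF2 genes 11 rose, with OSGIN1 at 0.52 ± 0.09 and HMOX1 at 0.47 ± 0.11 (12 adjusted over the list alone, adjusted p = 0.270 with an estimated correlation, and 7 rose without control replicate 2). The ATF4 list did not pass in PNA-21 (adjusted p = 0.142): 8 members rose and 5 fell (8 and 5 adjusted over the list alone).

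In all, 2388 genes were higher and 2296 lower in PNA-21, or 29.8% of those tested, 74 and 206 of them by at least 2-fold. Among the largest rises were SERPINB2 (1.78 ± 0.21), ATP6V0D2 (1.62 ± 0.21), PLCXD2 (1.29 ± 0.21), RENBP (1.31 ± 0.14), LINC01723 (1.73 ± 0.27), LINC02392 (1.65 ± 0.23) and LINC00520 (1.34 ± 0.18). The largest falls were in EPPIN (-1.95 ± 0.26), SLITRK6 (-1.92 ± 0.18), RANBP3L (-1.72 ± 0.34), the mucin MUC1 (-1.71 ± 0.11), ANGPT2 (-1.68 ± 0.22), CLEC3B (-1.66 ± 0.16), GRIP2 (-1.61 ± 0.16), MAP7D2 (-1.59 ± 0.18), COL3A1 (-1.55 ± 0.17) and SCUBE3 (-1.51 ± 0.10). MUC1 (ENSG00000185499, chromosome 1 from 155185824 to 155192916) went from 24.8 ± 1.38 CPM (SD, n = 3) in control to 7.54 ± 0.351 in PNA-21, and IGFBP3 (ENSG00000146674, chromosome 7 from 45912245 to 45921874), an insulin-like growth factor binding protein, from 623 ± 1.05 to 266 ± 32.1. MAGED4B, SPATC1L and MRPL23 met the rule for rises with wide spreads between libraries. MAGED4B was lost without PNA-21 replicate 1 (4.15). MRPL23 was lost in DESeq2 (1.31) and without PNA-21 replicate 3 (1.07). SPATC1L was lost in DESeq2 (2.99), without control replicate 2 (2.29) or 3 (2.55) and without PNA-21 replicate 1 (2.44) or 2 (3.10).

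The comparison of PNA-10b+21 with control asks what both sgPNAs in nanoparticles changed together, again beside untreated cells. The same lists led: 29 of 30 hypoxia and glycolysis genes fell (29 adjusted over the list alone, median -0.60), with CA9 at -1.12 ± 0.08, P4HA1 at -0.91 ± 0.07 and ALDOC at -0.85 ± 0.06 (adjusted p = 0.0999 with an estimated correlation). Of 29 matrix genes 24 fell and 1 rose (24 and 1 adjusted over the list alone), with COL5A1 at -1.11 ± 0.07, LOXL2 at -0.80 ± 0.06 and SPARC at -0.62 ± 0.06 (adjusted p = 0.106 with an estimated correlation). Of 25 cholesterol genes 20 rose (22 adjusted over the list alone), with DHCR7 at 0.53 ± 0.05, and this call held (adjusted p = 0.0396 with an estimated correlation). All but 1 of 30 G2 and M phase genes (29 adjusted over the list alone) and all but 1 of 32 S phase genes (31 adjusted over the list alone) rose, with AURKA at 0.58 ± 0.06, CCNB1 at 0.46 ± 0.06 and MCM7 at 0.41 ± 0.06. These had adjusted p = 0.132 with an estimated correlation for G2 and M phase and 0.135 for S phase genes.

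In PNA-10b+21, of 18 angiogenic factors 1 rose and 8 fell (2 and 9 adjusted over the list alone), with PDGFC at -0.47 ± 0.06 (adjusted p = 0.132 with an estimated correlation). Of 22 TGF-beta and SMAD genes 2 rose and 12 fell (2 and 16 adjusted over the list alone), with BMPER at -0.68 ± 0.07 (adjusted p = 0.135 with an estimated correlation). Of 20 chaperones 1 rose and 8 fell (1 and 11 adjusted over the list alone), with SEL1L at -0.29 ± 0.06 (adjusted p = 0.135 with an estimated correlation). Of 13 fatty acid genes 7 rose (7 adjusted over the list alone), with FASN at 0.67 ± 0.05 (adjusted p = 0.135 with an estimated correlation). Of 23 NRF2 genes 11 rose and 1 fell (12 and 1 adjusted over the list alone), with HMOX1 at 0.59 ± 0.11 and FTL at 0.33 ± 0.06 (adjusted p = 0.135 with an estimated correlation). Of 17 ERK feedback genes 7 rose and 1 fell (8 and 2 adjusted over the list alone), with FOSL1 at 0.53 ± 0.07 (adjusted p = 0.177 with an estimated correlation). In all, 2131 genes were higher and 2112 lower, 64 and 218 of them by at least 2-fold, and 1367 were higher without PNA-10b+21 replicate 1. Large rises included the glycosyltransferase GCNT3 (1.28 ± 0.17), RPS6KL1 (1.30 ± 0.20), LINC01723 (1.77 ± 0.27), ATP6V0D2 (1.56 ± 0.22), LINC02392 (1.53 ± 0.23), SERPINB2 (1.37 ± 0.22), LINC00520 (1.35 ± 0.18), LINC01363 (1.33 ± 0.21), DIRC3 (1.27 ± 0.19) and PAX8-AS1 (1.24 ± 0.13). Large falls included EPPIN (-2.14 ± 0.27), CLEC3B (-2.03 ± 0.17), ANGPT2 (-1.99 ± 0.23), RANBP3L (-1.85 ± 0.35), SLITRK6 (-1.83 ± 0.18), the metalloprotease ADAM28 (-1.73 ± 0.26), MUC1 (-1.67 ± 0.11), CYTIP (-1.65 ± 0.20), ZP1 (-1.64 ± 0.12) and COL3A1 (-1.60 ± 0.17).

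**Figure D1:**
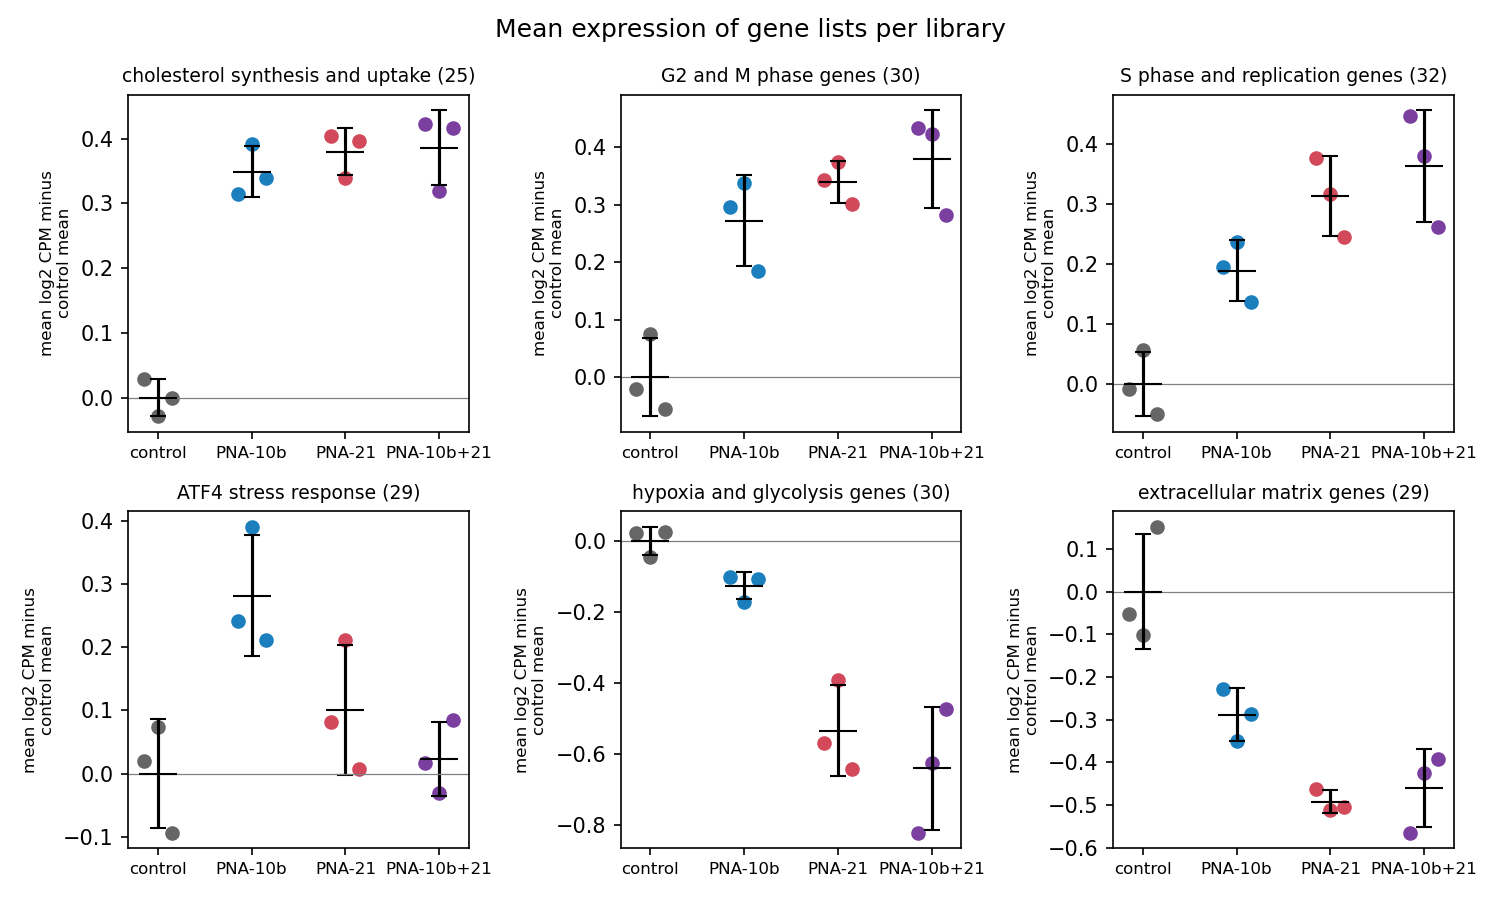
Mean log2 CPM of 6 gene lists in each library, as the difference from the control mean. Points are the 3 libraries of a group, and the bar with whiskers is their mean and SD. Cholesterol genes lie above control in all 3 treated groups, and hypoxia and glycolysis genes lie farther below control in PNA-21 and PNA-10b+21 than in PNA-10b.

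Setting PNA-10b+21 against PNA-10b asks what sgPNA-21 added when sgPNA-10b was present, with nanoparticles in both arms. Hypoxia and glycolysis genes fell here too, 25 of 30 (29 adjusted over the list alone, median -0.46), with CA9 at -0.99 ± 0.08, BNIP3 at -0.96 ± 0.10 and LOX at -0.91 ± 0.10 (adjusted p = 0.152 with an estimated correlation). ATF4 response genes, higher in PNA-10b, were lower after the addition: 14 of 29 fell (19 adjusted over the list alone), with NUPR1 at -0.54 ± 0.06 and STC2 at -0.60 ± 0.08 (adjusted p = 0.207 with an estimated correlation, and 8 fell without PNA-10b replicate 2). Of 29 matrix genes 9 fell (1 higher and 13 lower adjusted over the list alone), with LOXL2 at -0.68 ± 0.06 and FBN1 at -0.62 ± 0.08 (adjusted p = 0.350 with an estimated correlation). Of 17 heat shock genes 7 rose and 1 fell (9 and 1 adjusted over the list alone), with HSPH1 at 0.34 ± 0.06 and HSPA4 at 0.35 ± 0.06 (adjusted p = 0.181 with an estimated correlation). The heat shock count was 4 without PNA-10b replicate 2 and without PNA-10b+21 replicate 1 or 2. The cytokine gene IL6 (-1.01 ± 0.10), the tissue factor gene F3 (-0.93 ± 0.12) and IGFBP3 (-1.35 ± 0.07) fell, and CHI3L1 (0.86 ± 0.12), a secreted glycoprotein of glioma, rose.

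In that comparison 7 lists were higher and 8 lower by camera at the preset correlation, and 0 with an estimated one. By edgeR 724 genes were higher and 801 lower. The largest changes by the rule were rises of RPS6KL1 (1.10 ± 0.19), SECTM1 (1.05 ± 0.19), PAX8-AS1 (1.03 ± 0.13) and CCDC69 (0.90 ± 0.20), and falls of the metallothionein MT3 (-1.74 ± 0.21), ZP1 (-1.59 ± 0.12), IGFBP3 and ADAM28 (-1.29 ± 0.27). EEF1D (4.57 ± 1.13) and EIF3CL (-5.31 ± 0.93) also met the rule, each from very uneven libraries, and EEF1D did not pass without PNA-10b replicate 2 (4.5) or 3 (4.54) or PNA-10b+21 replicate 2 (0.88). The counts were 218 higher and 336 lower without PNA-10b+21 replicate 1, and 376 and 501 without PNA-10b+21 replicate 2. Without PNA-10b replicate 2 or 3 the higher counts were 446 and 363.

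The 2 single treatments at the same dose differed from each other in the direction of PNA-21 for hypoxia and glycolysis genes: 21 of 30 were lower in PNA-21 than in PNA-10b (27 adjusted over the list alone, median -0.38), with CA9 at -0.86 ± 0.08, ALDOC at -0.56 ± 0.06, PGK1 at -0.55 ± 0.07 and NDRG1 at -0.75 ± 0.10. Of 29 matrix genes 12 were lower (17 adjusted over the list alone), with LOXL2 at -0.64 ± 0.06 and COL5A1 at -0.63 ± 0.07. Both lists had adjusted p = 0.247 with an estimated correlation. Of 29 ATF4 genes 9 were lower (12 adjusted over the list alone), with VLDLR at -0.58 ± 0.08 and ATF3 at -0.34 ± 0.06 (adjusted p = 0.390 with an estimated correlation). Of 20 chaperones 4 were lower (6 adjusted over the list alone), with HERPUD1 at -0.27 ± 0.05 (adjusted p = 0.247 with an estimated correlation). Of 18 angiogenic factors 5 were lower (7 adjusted over the list alone), with VEGFA at -0.52 ± 0.07 (adjusted p = 0.272 with an estimated correlation). Higher in PNA-21 were 6 of 23 NRF2 genes (8 adjusted over the list alone), with NQO1 at 0.35 ± 0.07, 4 of 17 ERK feedback genes (5 adjusted over the list alone), with EPHA2 at 0.44 ± 0.07, and 3 of 17 heat shock genes (7 higher and 1 lower adjusted over the list alone), with HSPH1 at 0.23 ± 0.06. Each of these 3 lists had adjusted p = 0.247 with an estimated correlation. Also higher were 4 of 32 S phase genes (5 adjusted over the list alone) and 3 of 41 oxidative phosphorylation genes (8 adjusted over the list alone), with RFC3 at 0.37 ± 0.07 and CYC1 at 0.24 ± 0.06 (adjusted p = 0.459 with an estimated correlation for both). So were 2 of 31 p53 targets (3 adjusted over the list alone, adjusted p = 0.4085 with an estimated correlation) and 1 of 30 G2 and M phase genes (0 adjusted over the list alone, adjusted p = 0.670 with an estimated correlation). By camera 7 lists were thus higher and 5 lower at the preset correlation, and 0 with an estimated one. Beyond the lists, the collagenase MMP1 (1.00 ± 0.18), BEX1 (0.80 ± 0.10), CCDC69 (0.95 ± 0.19), RPS6KL1 (0.95 ± 0.20) and SERPINB2 (0.79 ± 0.18) were higher in PNA-21. MT3 (-1.54 ± 0.21), ZP1 (-1.44 ± 0.12), the myeloid receptor gene TREM1 (-1.34 ± 0.14), METRNL (-1.33 ± 0.38) and IGFBP3 (-1.30 ± 0.07) were lower. In all 458 genes were higher and 609 lower. The counts were 181 and 373 without PNA-10b replicate 1, and 199 and 377 without PNA-21 replicate 1. Without PNA-10b replicate 2 the higher count was 285, and without PNA-21 replicate 2 it was 282. SERPINB2 did not pass without PNA-10b replicate 1 (0.72) or PNA-21 replicate 2 (0.57). METRNL did not pass in DESeq2 (-1.33), without control replicate 1 (-1.34), PNA-10b replicates 1 (-1.43), 2 (-1.15) or 3 (-1.40), or PNA-21 replicates 2 (-1.22) or 3 (-1.18).

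Setting PNA-10b+21 against PNA-21 asks what sgPNA-10b added when sgPNA-21 was present. Here too the total dose was higher in the combined arm. By edgeR 0 genes were higher and 0 lower, with a smallest adjusted p of 0.266. At an unadjusted p under 0.05 there were 427 higher and 927 lower, or 8.6% of genes. limma voom called 0, and DESeq2 called 0 higher and 25 lower. The 95% interval of the change lay within 1.5-fold for 75.4% of genes. The 5 genes with the smallest p were AHR, the aryl hydrocarbon receptor (-0.39 ± 0.09), the cytochrome c gene CYCS (-0.34 ± 0.08), LYRM1 (-0.26 ± 0.06), UMAD1 (-0.42 ± 0.10) and SCAMP1 (-0.44 ± 0.10), each with an adjusted p of 0.266. Of these AHR and CYCS passed in DESeq2, which gave no adjusted p for LYRM1 and UMAD1. In this comparison DESeq2 gave none for 11273 of 15715 genes, so its adjustment covered fewer genes than that of edgeR. By camera at the preset correlation 7 lists passed, with 0 members called by edgeR in each. Higher were G2 and M phase genes (median 0.06), S phase genes (0.06) and cytosolic ribosomal proteins (0.04). Lower were hypoxia and glycolysis genes (-0.07), ATF4 genes (-0.07), NF-kB genes (-0.10, with 4 lower adjusted over the list alone) and reported targets of miR-10b (-0.04). Each had adjusted p = 0.863 with an estimated correlation, and adjusted over the list alone the other 6 lists had 0 members.

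The 2 sgPNAs were compared with additive effects through genes measured on different libraries. The effect of an sgPNA alone was taken against untreated control, so it includes any effect of the nanoparticles. Across 15715 genes, which are not independent replicates, the effect of sgPNA-21 alone and its effect on top of sgPNA-10b had r = 0.409 ± 0.0900 (jackknife SE over libraries) and rho = 0.438. Over the 4684 genes called in PNA-21 the slope was 0.362 and 81.7% kept their sign. For sgPNA-10b the effect alone and that on top of sgPNA-21 had r = -0.063 ± 0.130 and rho = -0.099. Over the 1019 genes called in PNA-10b the slope was 0.02 and 41.3% kept their sign, and their median absolute change was 0.057 on top of sgPNA-21, beside 0.32 alone.

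**Figure D2:**
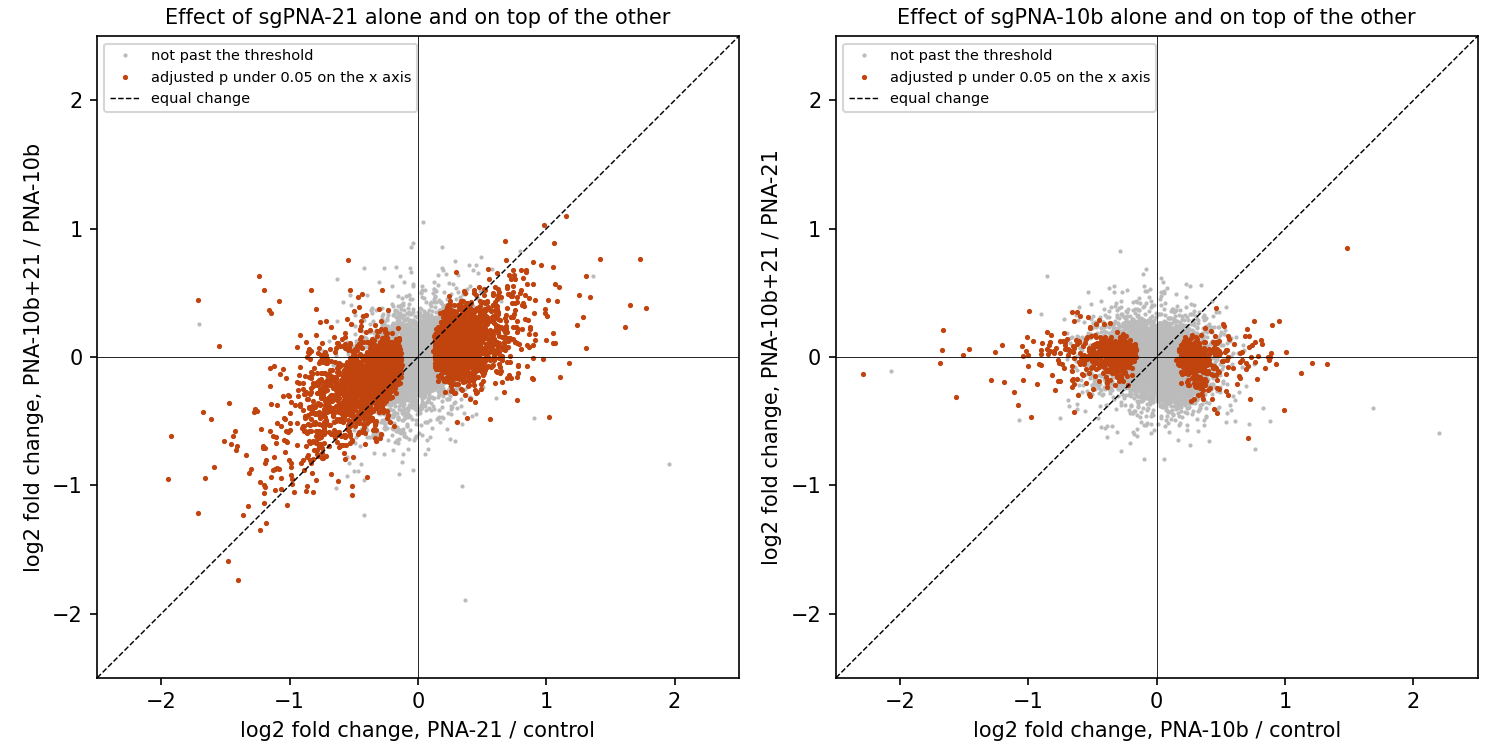
Log2 fold changes across genes with a mean log2 CPM of at least 1. The x axis is the change with an sgPNA alone against untreated control (sgPNA-21 on the left, sgPNA-10b on the right). The y axis is the effect of that sgPNA on top of the other, and the dashed line marks equal change. Genes called on the x axis follow the line in part for sgPNA-21 (slope 0.362) and lie flat for sgPNA-10b (slope 0.02); genes beyond the axes are not shown.

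The interaction passed the test for 233 genes above and 258 below additivity. By camera 8 lists lay above and 7 below at the preset correlation, and 0 and 1 with an estimated one. Cholesterol genes lay below it: 14 of 25 (20 adjusted over the list alone), with HMGCS1 at -0.69 ± 0.08, IDI1 at -0.65 ± 0.11, INSIG1 at -0.52 ± 0.08 and MSMO1 at -0.84 ± 0.14, and this call held with an estimated correlation (adjusted p = 0.0114). Of 29 ATF4 genes 12 lay below (1 above and 19 below adjusted over the list alone), with SLC7A11 at -0.86 ± 0.15 and PSAT1 at -0.81 ± 0.14. Of 29 matrix genes 13 lay above (20 adjusted over the list alone), with COL1A1 at 0.54 ± 0.09 and COL1A2 at 0.53 ± 0.10. Both lists had adjusted p = 0.172 with an estimated correlation. The combined change of these genes was thus smaller than the sum of the single changes. A change common to all 3 treated groups enters the interaction with its sign turned, and no arm with nanoparticles alone separates it. The counts above and below were 46 and 50 without PNA-10b replicate 2, 60 and 49 without control replicate 1, 72 and 59 without control replicate 3, 70 and 59 without PNA-21 replicate 2, 87 and 74 without PNA-10b+21 replicate 2, 97 and 171 without PNA-10b+21 replicate 3, 151 and 116 without PNA-10b replicate 3, and 456 and 598 without control replicate 2. Without PNA-10b replicate 1 the count below was 547.

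The 3 treatments changed many of the same genes against the same controls. PNA-10b and PNA-21 shared 381 higher genes, beside 65.6 for independent calls, and 505 lower genes, beside 85.8, with 3 and 1 called in opposite directions. Genes called the same way in both numbered 420 without control replicate 1, 1115 without 2 and 358 without 3. PNA-10b and PNA-10b+21 shared 350 higher, beside 58.6, and 471 lower, beside 78.9. PNA-21 and PNA-10b+21 shared 1637 higher, beside 323.8, and 1676 lower, beside 308.6. In 20 simulations of unchanged groups against the same controls the highest shared count was 1. Unchanged groups give almost no calls, so this count does not measure what shared controls add where genes do change. The covariance of the changes was 0.0685 for PNA-10b and PNA-21, beside 0.0216 in the simulations. It was 0.0646 for PNA-10b and PNA-10b+21, beside 0.0218, and 0.113 for PNA-21 and PNA-10b+21, beside 0.0218. Since 3 controls cannot be divided into 2 sets of 2, part of the excess over independent calls can come from the shared controls.

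Reported targets of a microRNA did not rise as a group under the sgPNA made against it. Whether either microRNA was blocked was not measured. Of 52 tested targets of miR-21, 8 rose and 12 fell in PNA-21 and 7 rose and 15 fell in PNA-10b+21, with the same counts adjusted over the list alone. The list lay low by camera at the preset correlation in both, with adjusted p = 0.245 with an estimated correlation in PNA-21 and 0.132 in PNA-10b+21. In PNA-21 that call was also lost without control replicate 2 (adjusted p = 0.0583) or PNA-21 replicate 3 (adjusted p = 0.0953) and with the replicate number as a block (adjusted p = 0.0531). PDCD4 (ENSG00000150593, chromosome 10 from 110871795 to 110900006), a translation inhibitor and a much used readout of miR-21, changed by -0.27 ± 0.07 in PNA-21 (adjusted p = 0.00772) and -0.31 ± 0.07 in PNA-10b+21 (adjusted p = 0.00282). The metalloprotease inhibitor TIMP3 fell by 0.91 ± 0.07 and 0.82 ± 0.07, and TGFBI fell by 0.68 ± 0.07 and 0.64 ± 0.07. SPRY2, an inhibitor of ERK signalling, rose by 0.48 ± 0.06 and 0.49 ± 0.06. IGFBP3, also on this list, was lower in PNA-21 than in PNA-10b (-1.30 ± 0.07, adjusted p = 8.36e-11 by edgeR). It was also lower in PNA-10b+21 than in PNA-10b (-1.35 ± 0.07, adjusted p = 4.27e-11 by edgeR). Each was the smallest adjusted p of all genes in its comparison. SPRY1 was at -0.34 ± 0.21 in PNA-21 and -0.63 ± 0.22 in PNA-10b+21, the second past the threshold in edgeR (adjusted p = 0.0402) and not in DESeq2, and not without control replicate 1 (-0.68), 2 (-0.68) or 3 (-0.55) or PNA-10b+21 replicate 1 (-0.40) or 2 (-0.58). RECK (-0.15 ± 0.07 in both), BTG2 (-0.11 ± 0.13 and -0.08 ± 0.13) and RHOB (-0.13 ± 0.12 and -0.10 ± 0.12) did not pass, although RECK did without control replicate 1 (-0.21 and -0.20). In PNA-10b, which lacked sgPNA-21, TIMP3 (-0.27 ± 0.07) and RHOB (-0.43 ± 0.13) fell past the threshold by edgeR. TGFBI (-0.22 ± 0.07), PDCD4 (-0.17 ± 0.07) and SPRY2 (0.14 ± 0.06) did not pass there.

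Of 35 tested targets of miR-10b, 1 rose and 1 fell in PNA-10b (1 and 1 adjusted over the list alone), and 8 rose and 6 fell in PNA-10b+21 (9 and 7 adjusted over the list alone); the list did not pass in either (adjusted p of 0.210 and 0.497). In PNA-21 11 rose and 3 fell (14 and 4 adjusted over the list alone, adjusted p = 0.316 with an estimated correlation). That camera call was lost without control replicate 2 (adjusted p = 0.0526) or 3 (adjusted p = 0.0586) and without PNA-21 replicate 1 (adjusted p = 0.0677) or 2 (adjusted p = 0.0847). HOXD10, the classic target, had 0.680 ± 0.112 CPM (SD, n = 3) in control and was at 0.37 ± 0.32 in PNA-10b (adjusted p = 0.590). BCL2L11, a death-promoting BCL2 relative, fell by 0.55 ± 0.15 in PNA-10b (adjusted p = 0.0264), a call lost in DESeq2 and without control replicate 1 (-0.54) or 3 (-0.53) or PNA-10b replicate 1 (-0.52), 2 (-0.65) or 3 (-0.49). In PNA-10b the other targets were at 0.51 ± 0.26 (TFAP2C), -0.03 ± 0.05 (CDKN1A), 0.03 ± 0.05 (NF1), -0.11 ± 0.09 (KLF4) and -0.23 ± 0.12 (EPHA4), none past the threshold by edgeR. DESeq2 called none of the last 4 and gave no adjusted p for TFAP2C, nor for HOXD10. In PNA-10b+21 TFAP2C rose by 0.90 ± 0.25 (adjusted p = 0.0108, lost without PNA-10b+21 replicate 2 at 0.77) and CDKN1A by 0.23 ± 0.05. There KLF4 fell by 0.30 ± 0.09, a call lost in DESeq2 and without control replicate 1 (-0.28) or 2 (-0.29) or PNA-10b+21 replicate 1 (-0.25), and BCL2L11 by 0.49 ± 0.15, lost in DESeq2 and without PNA-10b+21 replicate 3 (-0.37). In PNA-21 CDKN1A rose by 0.19 ± 0.05, and EPHA4 fell by 0.35 ± 0.12, lost without control replicate 2 (-0.35) or 3 (-0.27) or PNA-21 replicate 2 (-0.38) or 3 (-0.24).

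**Figure D3:**
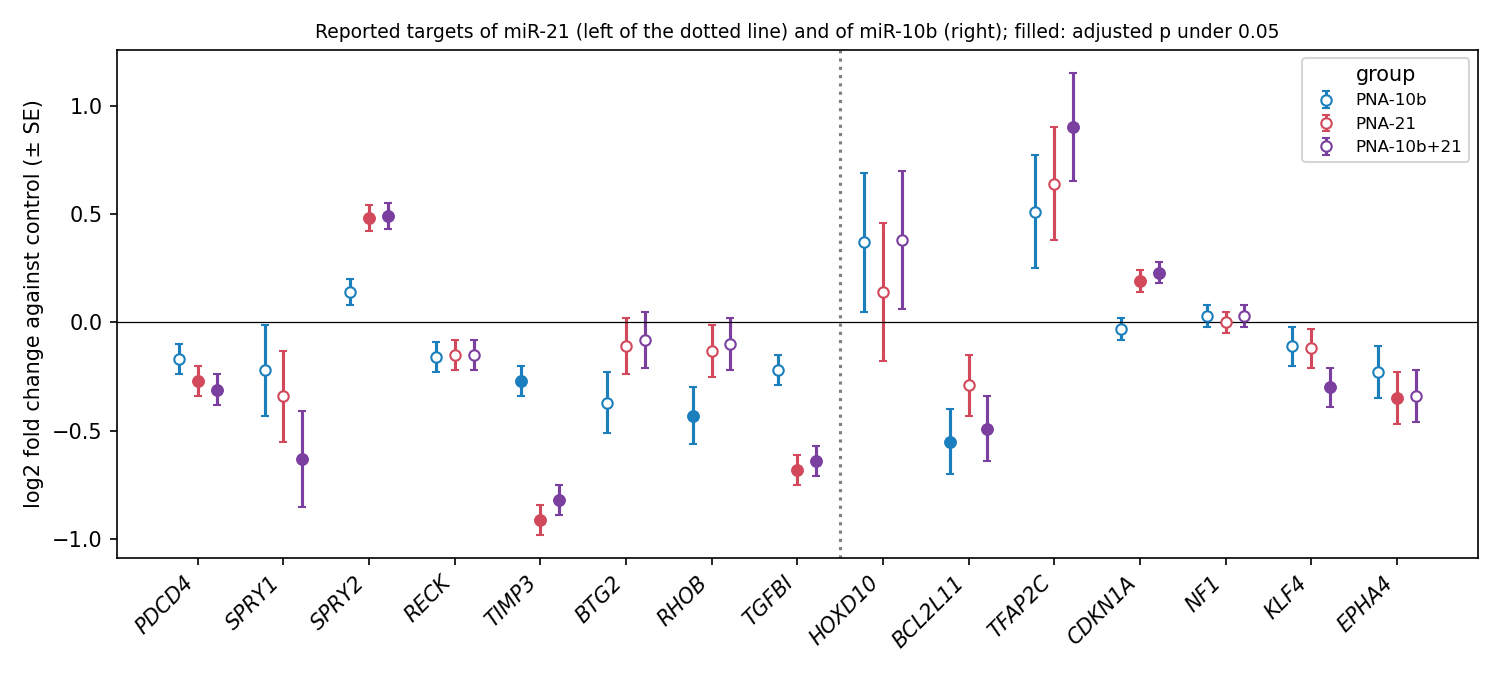
Log2 fold change against control (± SE, n = 3 per group) of 8 reported targets of miR-21 and 7 of miR-10b in PNA-10b, PNA-21 and PNA-10b+21. Filled points pass an adjusted p of 0.05. TIMP3, TGFBI and PDCD4 lie below 0 and SPRY2 above 0 in PNA-21 and PNA-10b+21. They have the same signs in PNA-10b, where only TIMP3 among them passes.

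Transcripts with a seed site were compared with those without one. The 1269 genes with a miR-21 site differed from genes without one by a median of 0.016 log2 in PNA-21 (jackknife SE 0.0257), -0.022 in PNA-10b+21 (SE 0.0173) and -0.038 in PNA-10b+21 against PNA-10b (SE 0.0217). By camera the adjusted p of these was 0.794, 0.794 and 0.098. The 1834 genes with a miR-10b site differed by 0.003 in PNA-10b (SE 0.00661), -0.014 in PNA-10b+21 (SE 0.0110) and -0.005 in PNA-10b+21 against PNA-21 (SE 0.0104). Their adjusted p was 0.917, 0.794 and 0.826. Among 15934 7mers ranked from the highest, the miR-21 site stood at 5780 in PNA-21 and the miR-10b site at 5855 in PNA-10b. In PNA-21 against PNA-10b the miR-21 site stood at 944, with 5.92% of 7mers as high, while the median difference there was 0.004 (camera adjusted p = 0.917). In PNA-10b+21 against PNA-21, miR-21 site genes lay lower by -0.04 at the preset correlation (camera adjusted p = 0.00288). That call was lost over the same 14 tests (adjusted p = 0.384 with an estimated correlation), and 14.9% of 7mers were as low before the regression on UTR length and GC content and 23.1% after it. The difference itself was -0.039 before that regression and -0.0026 after it. In the interaction miR-21 site genes lay at -0.061 (camera adjusted p = 0.0318, and adjusted p = 0.526 with an estimated correlation). After the regression the miR-21 site difference was -0.0079 in the interaction and -0.0021 in PNA-10b+21 against PNA-10b. The median in PNA-21 was 0.034 without control replicate 2 and 0.033 without PNA-21 replicate 1. In PNA-10b+21 it was -0.009 without control replicate 2 and -0.011 without PNA-10b+21 replicate 1. The miR-10b median was -0.006 in PNA-10b+21 without PNA-10b+21 replicate 2. It was -0.002 in PNA-10b without control replicate 1, and 0.006 without control replicate 3 or PNA-10b replicate 1. In PNA-10b+21 against PNA-21 it was 0.001 without PNA-10b+21 replicate 2, -0.012 without PNA-10b+21 replicate 3 and 0 without PNA-21 replicate 2. Of 6 host loci of the microRNAs tested, 0 were called by edgeR in PNA-10b, PNA-21 or PNA-10b+21. VMP1, which overlaps MIR21, was at -0.10 ± 0.06, 0.05 ± 0.06 and -0.08 ± 0.06. Counts per library were low for HOXD3 (4 to 20) and HOXD9 (18 to 38), and MIR10B (0 to 7) was not tested.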

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

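Of the tests in this part, those on shared controls, on handling common to all treated samples, on one axis of change and on UTR length and GC content, and the adjustment of the site tests with an estimated correlation, were chosen only after the result was seen.

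A difference between groups brought up the interaction: the interaction term passed the test for 233 genes above additivity and 258 below. The effect of sgPNA-21 alone was taken against untreated control. A change common to all treated groups thus enters this contrast with its sign turned. With no arm of nanoparticles alone, the test cannot tell such a change from an sgPNA-21 effect that depends on sgPNA-10b. By the rule for named genes, RANBP3L (2.16), TMEM119 (1.88), CEMIP (1.72), COL3A1 (1.64) and ITGA11 (1.53) lay above additivity. Below it lay SERPINB2 (-1.40), ATP6V0D2 (-1.38), ECM2 (-1.35), LINC02392 (-1.25) and PARD6B (-1.10). TMEM119, CEMIP, COL3A1, ITGA11 and ECM2 passed without each library in turn. With 1 library left out, RANBP3L passed only without control replicate 2, PNA-10b replicate 1 or PNA-21 replicate 3, with 1.79 (without PNA-10b replicate 2) to 2.61 (without PNA-10b replicate 1). DESeq2 gave no adjusted p for RANBP3L, SERPINB2, ATP6V0D2, ECM2, LINC02392 and PARD6B here. SERPINB2 did not pass without control replicate 1 (-1.39), nor ATP6V0D2 without control replicate 1 (-1.38) or PNA-10b replicate 2 (-1.21). LINC02392 did not pass without control replicates 1 (-1.11) or 3 (-1.07), PNA-10b replicates 2 (-1.24) or 3 (-1.16), PNA-21 replicates 2 (-1.23) or 3 (-1.17), or PNA-10b+21 replicates 2 (-1.34) or 3 (-1.04). PARD6B did not pass without control replicates 1 (-1.06) or 3 (-1.01), PNA-10b replicates 2 (-1.12) or 3 (-1.04), PNA-21 replicates 2 (-1.06) or 3 (-1.05), or PNA-10b+21 replicates 1 (-1.01) or 2 (-1.14). Of 100 groupings of the 12 libraries into 4 groups, 3 called as many genes, the real one with 491 included. The highest other called 1046. Of the 19 other groupings with all 3 controls on one side of the contrast, 4 called 174, 287, 610 and 1046 genes and 15 called 6 or fewer. The 80 groupings with controls on both sides called at most 1. No further test of this structure was made.

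The splits of the 6 libraries of a comparison number 10, the real one included, too few for a share under 0.05. In PNA-10b against control 1 split called as many genes (real 1019, highest other 6), in PNA-21 against control 1 (4684 and 1), and in PNA-10b+21 against control 1 (4243 and 0). Between treatments it was 1 for PNA-10b+21 against PNA-10b (1525 and 2), 1 for PNA-21 against PNA-10b (1067 and 1), and 10 for PNA-10b+21 against PNA-21 (0 and 6).

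The first pattern is that the 3 treatments move the same genes the same way. The covariance of the PNA-10b and PNA-21 changes was 0.0685 and the highest simulated one 0.0231. This argues against the shared controls as the whole cause of the pattern only where control libraries vary as simulated. On the first principal component the controls lay at -22.9, -20.3 and -32.4, and a spread shared by many genes may widen the simulated range. A single control library is argued against with the same limit. Less 1.5 times the simulated covariance, the covariance was 0.0513, 0.0626 and 0.0374 without control 1, 2 and 3. Genes called the same way then numbered 420, 1115 and 358. Handling common to all treated samples may not carry all of the PNA-21 change, because 1067 genes differed between PNA-21 and PNA-10b at the same dose. For the PNA-10b change it cannot be told apart from an effect of sgPNA-10b that sgPNA-21 already reaches, since that change was absent on top of sgPNA-21 (r = -0.063) and no arm had nanoparticles alone.

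The second pattern is that hypoxia and glycolysis genes fall in PNA-21 and PNA-10b+21. GC content and transcript length are argued against, as the list median in PNA-21 was -0.52 before and -0.45 after the regression on both. One axis of change shared with PNA-10b would put the list median at -0.26 in PNA-10b, and the median there was -0.09. Its bootstrap SE of 0.023 is over list genes, which are not replicates, and leaves out the spread between libraries. By library the list mean in PNA-10b lay from -0.17 to -0.1 relative to control. These values argue against 1 axis for this list, with a slope from genes called in PNA-21 against the same controls. The prediction also missed cholesterol (0.35 beside 0.2) and G2 and M phase genes (0.27 beside 0.17). It came nearer for matrix (-0.22 beside -0.27) and S phase genes (0.18 beside 0.15). Culture density or medium at harvest was not recorded in the labels, so a difference in oxygen supply between wells stays open beside an effect of sgPNA-21.

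The third pattern is that miR-21 site genes lie lower in PNA-10b+21 than in PNA-21, a call at the preset correlation alone (adjusted p = 0.384 with an estimated correlation). The difference was -0.039 before a regression on UTR length and GC content and -0.0026 after it, where the SD over 7mers was 0.0067. Most of the difference thus went with UTR length and GC content, and an effect of the site cannot be told apart from them. Before the regression 14.87% of 7mers lay as low as the miR-21 site, and 23.11% after it. The ranking thus did not single out the site in either case. No biological explanation was tested.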

How the results depend on the processing

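The compared groups alone with genes filtered anew, and each library left out with genes filtered anew, were chosen only after a first result was seen. The other alternatives were planned. In the planned fits on fewer libraries the 15715 genes were kept, a choice made after that first run.

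By other tools many of the same genes were called. DESeq2 shared 874 of 1019 genes in PNA-10b, 3976 of 4684 in PNA-21 and 3611 of 4243 in PNA-10b+21 against control, and limma voom shared 965, 4577 and 4145. With the replicate number as a block more genes were called: 1271 beside 1019 in PNA-10b, 4851 beside 4684 in PNA-21, and 4407 beside 4243 in PNA-10b+21. The interaction then had 710 beside 491, and PNA-10b+21 against PNA-21 still 0. With no filter, which tests all 35741 genes, the higher count in PNA-10b was 690, PNA-10b+21 against PNA-21 had 32 higher and 300 lower, and the interaction 350 above and 724 below. For PNA-10b+21 against PNA-21, DESeq2 called 25 lower, the compared groups alone 10 lower, and the same with genes filtered anew 1 higher and 47 lower; the cause was not tested.

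The correlation for sgPNA-21 was 0.472 with genes of 1 CPM in 3 libraries and 0.606 in the upper part of expression, where that for sgPNA-10b was -0.203. At an adjusted p of 0.01 the shared higher and lower genes were 107 and 230 for PNA-10b and PNA-21, 103 and 218 for PNA-10b and PNA-10b+21, and 940 and 1056 for PNA-21 and PNA-10b+21, fewer because the threshold is stricter. With 8mer sites only, the miR-21 median was 0.046 in PNA-21 and -0.015 in PNA-10b+21, and the miR-10b median -0.053 in PNA-10b+21 and -0.020 against PNA-21. With at least 2 sites the miR-21 median was -0.022 in PNA-21, -0.071 in PNA-10b+21 and -0.085 against PNA-10b, and the miR-10b median 0.009 in PNA-10b and -0.007 in PNA-10b+21. The cause was not tested.

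With 1 library left out, the 2 that remain in its group are assumed to vary like the other groups. Counts higher and lower ran from 99 to 586 and 207 to 687 in PNA-10b, 1652 to 2402 and 1767 to 2344 in PNA-21, and 1367 to 2130 and 1408 to 2151 in PNA-10b+21 against control. They ran from 218 to 815 and 336 to 895 in PNA-10b+21 against PNA-10b, 181 to 486 and 373 to 688 in PNA-21 against PNA-10b, and 46 to 456 and 49 to 598 in the interaction. PNA-10b+21 against PNA-21 had 0 by edgeR without each library. The correlations ran from 0.333 to 0.428 for sgPNA-21 and -0.135 to -0.013 for sgPNA-10b. The miR-21 medians ran from 0.008 to 0.034 in PNA-21, -0.027 to -0.009 in PNA-10b+21 and -0.052 to -0.030 against PNA-10b. The miR-10b medians ran from -0.002 to 0.006 in PNA-10b, -0.020 to -0.006 in PNA-10b+21 and -0.012 to 0.001 against PNA-21. With genes filtered anew the counts ran from 98 to 576 and 208 to 676 in PNA-10b, 1650 to 2424 and 1758 to 2334 in PNA-21, and 1334 to 2169 and 1414 to 2132 in PNA-10b+21 against control. They ran from 193 to 772 and 339 to 915 in PNA-10b+21 against PNA-10b, 194 to 481 and 351 to 685 in PNA-21 against PNA-10b, and 44 to 451 and 48 to 577 in the interaction, with 0 by edgeR in PNA-10b+21 against PNA-21. The correlations then ran from 0.299 to 0.363 for sgPNA-21, each below the 0.409 of all libraries, and from -0.148 to -0.043 for sgPNA-10b; over 16015 to 16082 genes, the cause was not tested.

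Of 143 named results, each a gene in 1 comparison, 119 kept their side of the threshold with DESeq2, 8 lost it, 3 passed it, and 13 had no adjusted p there. Of 75 list calls by camera, in the 3 comparisons against control and PNA-10b+21 against PNA-10b, 64 held by fry and 5 with an estimated correlation, and 70 did not hold with the latter. No direction of a called result reversed under these alternatives. The simulated data varied the fold alone, among genes with an average log2 CPM of at least 1. Recovery by depth or level, and below that level, was thus not tested. Of the smallest simulated changes 58.2% were recovered in PNA-10b.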

Other observations

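The lists below were fixed with the others and are given as values; no test in this part was chosen after its result was seen. Against control, in PNA-10b, PNA-21 and PNA-10b+21 in that order, counts are higher and lower genes at an adjusted p of 0.05 over all genes, and a list is said to pass by camera at the preset correlation.

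In PNA-10b 5 of 30 hypoxia and glycolysis genes fell (5 adjusted over the list alone), with ADM at -0.37 ± 0.07, and the list passed (adjusted p = 0.516 with an estimated correlation). Without control replicate 3 there were 2 and without PNA-10b replicate 2 there was 1. Heat shock genes had 0 and 2, 7 and 1, and 10 and 2 of 17, and passed in PNA-21 (adjusted p = 0.305 with an estimated correlation) and PNA-10b+21 (adjusted p = 0.159 with an estimated correlation), with HSPE1 at 0.68 ± 0.12 in PNA-21. The PNA-21 heat shock count was 4 without control replicate 2 (camera adjusted p = 0.0795) or PNA-21 replicate 1, and the PNA-10b+21 count 5 without PNA-10b+21 replicate 1 or 2. Oxidative phosphorylation genes had 0 and 0, 13 and 0, and 11 and 0 of 41, and passed in the last 2 (adjusted p = 0.465 and adjusted p = 0.393 with an estimated correlation), with CYC1 at 0.43 ± 0.07 in PNA-21. Its count in PNA-21 was 6 without control replicate 3, 5 without PNA-21 replicate 1 and 7 without PNA-21 replicate 2, the call was lost without control replicate 2 (adjusted p = 0.0607), and the PNA-10b+21 count was 7 without PNA-10b+21 replicate 2. Matrix proteases had 3 and 10 of 24 in PNA-21 and 4 and 10 in PNA-10b+21, and passed in both (adjusted p = 0.183 and adjusted p = 0.135 with an estimated correlation), with PLAT at -0.79 ± 0.09 in PNA-21.

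Inflammatory genes of NF-kB had 5 and 2, 11 and 5, and 6 and 6 of 26, and passed in PNA-10b (adjusted p = 0.433 with an estimated correlation) and PNA-21 (adjusted p = 0.445 with an estimated correlation); the cytokine gene IL1B rose by 0.54 ± 0.08 in PNA-10b and 0.86 ± 0.08 in PNA-21, and ICAM1 changed by -0.44 and -0.85. The PNA-10b count was 2 without control replicate 1 or 3, 9 without control replicate 2, 3 without PNA-10b replicate 2 and 2 without PNA-10b replicate 3 (camera adjusted p = 0.205), and the PNA-21 count 7 without PNA-21 replicate 2. The PNA-21 call was lost without control replicate 1 (adjusted p = 0.101) or 3 (adjusted p = 0.0770) and without PNA-21 replicate 2 (adjusted p = 0.0741). Interferon-stimulated genes had 0 and 2, 4 and 11, and 4 and 9 of 30, and passed in PNA-10b (adjusted p = 0.211 with an estimated correlation), with IFIT1 at -0.76 ± 0.13 and 1 lower without control replicate 3 or PNA-10b replicate 2. Immediate early genes had 2 and 5 of 22 in PNA-21 and in PNA-10b+21 (adjusted p of 0.150 and 0.190). Histone genes had 0 and 4 and 0 and 3 of 10 there (adjusted p of 0.136 and 0.0804). Lysosome and autophagy genes had 1 and 3, 5 and 8, and 5 and 8 of 27, and passed in PNA-10b (adjusted p = 0.440 with an estimated correlation), where 0 fell without control replicate 1 or PNA-10b replicate 2, 7 without control replicate 2 and 1 without PNA-10b replicate 1, and the call was lost without control replicate 1 (adjusted p = 0.135) or 3 (adjusted p = 0.0589).

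Mesenchymal transition genes had 0 and 4, 1 and 7, and 1 and 10 of 22 and passed in each (adjusted p = 0.420, adjusted p = 0.349 and adjusted p = 0.272 with an estimated correlation), with FN1 at -0.44 in PNA-10b and -0.70 in PNA-21. The lower count was 4 in PNA-21 without control replicate 3 or PNA-21 replicate 3, and 6 in PNA-10b+21 without PNA-10b+21 replicate 1. Targets of YAP and TAZ had 1 and 3, 2 and 7, and 0 and 6 of 21, and passed in the last 2 (adjusted p = 0.490 and adjusted p = 0.399 with an estimated correlation), with 4 lower in PNA-21 without PNA-21 replicate 3 (adjusted p = 0.254) and the call lost too without control replicate 2 (adjusted p = 0.0733). Glioma stem cell and astrocyte genes had 0 and 3, 2 and 6, and 1 and 6 of 14 and passed in each (adjusted p = 0.0737, adjusted p = 0.138 and adjusted p = 0.111 with an estimated correlation), with the glutamate transporter SLC1A3 at -0.56 ± 0.08 in PNA-10b and -0.92 ± 0.09 in PNA-21, and 1 lower in PNA-10b without control replicate 1 or 3 or PNA-10b replicate 2. Nuclear noncoding RNAs had 0 and 3, 2 and 3, and 2 and 4 of 10, and passed in PNA-10b (adjusted p = 0.433 with an estimated correlation), with MEG3 at -0.71 ± 0.09 and 1 lower without control replicate 3 or PNA-10b replicate 2. That call was lost without control replicate 2 (adjusted p = 0.166) and without PNA-10b replicate 1 (adjusted p = 0.0768) or 2 (adjusted p = 0.1001). Metallothioneins had 0 and 0, 1 and 4, and 0 and 3 of 7 and passed in PNA-10b+21 (adjusted p = 0.309 with an estimated correlation), a call lost without control replicate 1 (adjusted p = 0.164), PNA-10b replicate 1 (0.0568), 2 (0.0514) or 3 (0.0584), PNA-21 replicate 1 (0.0509) and PNA-10b+21 replicate 1 (0.0812) or 3 (0.0746), and with the replicate number as a block (0.0628).

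Targets of p53 had 2 and 0, 9 and 3, and 6 and 3 of 31 (adjusted p of 0.996, 0.150 and 0.288), apoptosis regulators 2 and 2, 9 and 4, and 9 and 5 of 30 (0.542, 0.150 and 0.498), and genes of PI3K, AKT and FOXO 1 and 1, 3 and 5, and 2 and 6 of 27 (0.974, 0.776 and 0.425). The median and mean of the p53 list differ in sign in PNA-10b+21 (-0.02 and 0.04), and those of the PI3K list in PNA-21 (-0.01 and 0.04). The microRNA machinery had 0 and 0, 1 and 2, and 3 and 1 of 12 (0.542, 0.990 and 0.548), with AGO2 at 0.24 in PNA-21. Cytosolic ribosomal proteins had 0 and 1, 0 and 0, and 1 and 0 of 75 (0.974, 0.803 and 0.189).

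Markers of other cell types were read for RNA from other cells. Neuron markers had 0 and 0, 0 and 5, and 0 and 4 of 8, and passed in PNA-10b+21 (adjusted p = 0.255 with an estimated correlation), a call lost without control replicate 2 (adjusted p = 0.0834) or 3 (0.0630), PNA-10b replicate 1 (0.0540), 2 (0.0541) or 3 (0.0502), PNA-21 replicate 1 (0.0509) or 3 (0.0515) and PNA-10b+21 replicate 1 (0.0583) or 2 (0.0810), and with the replicate number as a block (0.0562). Oligodendrocyte markers had 0 and 0, 1 and 1, and 0 and 0 of 4, endothelial markers 0 and 2, 0 and 2, and 0 and 1 of 7, and epithelial markers 0 and 0 in each of 6. Microglia and macrophage markers had 0 and 3, 0 and 2, and 0 and 3 of 3 and passed in each. The call held in PNA-10b with an estimated correlation (adjusted p = 0.0476) and not in PNA-21 (adjusted p = 0.103) or PNA-10b+21 (adjusted p = 0.0999), and 1 was lower in PNA-10b without PNA-10b replicate 2. Of them CD74, at 332.68 CPM over all libraries, changed by -0.35, -0.48 and -0.50, and CSF1R by -0.36, -0.72 and -0.59. The third member, HLA-DRA, changed by -3.17, -1.96 and -4.23, the second not past the threshold, and its control level rests on 1 library: 14.77 CPM in control replicate 3 beside 1.27 and 0.71 in the others. The list mean was -1.30 in PNA-10b and its median -0.36.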
